A study of Mus musculus with 3 samples.

How the data were processed

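The series measured medial prefrontal cortex (mPFC), a frontal region of the mouse cortex, from untreated C57BL/6 mice aged 3 months. It holds 3 samples, 1 per assay: DNA enriched with an antibody against methylated cytosine (MeDIP), unenriched input DNA, and RNA. The design text states 5 replicates for MeDIP, 5 input samples pooled for sequencing, and 3 replicates for RNA-seq. The RNA-seq gene table was the file used, and the MeDIP and input DNA data were not analysed here. The labels give no treatment and no second condition, so nothing was compared between conditions.

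Per the labels' protocols, RNA was extracted with a phenol-based reagent, treated with DNase and made into libraries with the Illumina TruSeq RNA Sample Preparation v2 kit. Per the submitters' processing notes, CASAVA 1.8.2, TopHat and Cufflinks were used for the RNA data with the mouse build mm10. The versions of TopHat and Cufflinks, the annotation release, the handling of strand and the combining of replicates are not given in the sources used here. The values the authors deposited are FPKM, fragments per kilobase of transcript and per 1000000 mapped fragments, for 46073 Ensembl gene identifiers. FPKM is divided by an effective transcript length, so it allows genes to be ranked within a sample. Errors in the assumed length, the isoform mix or the mapping of repeated sequence enter every comparison between genes.

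The file has 2 value columns, and they hold the same value in 46073 of 46073 rows. They were counted as 1 sample, with 1 value per gene. No spread between replicates could be computed, so no value has an error and no difference between genes has a replicate check or a p-value. The limma test planned for gene pairs, the planned spread and shift between libraries, and leaving out each library needed separate libraries and were not run. Of the rule for named genes, the part on spread between libraries was not used. The planned analysis of CpG content at promoters needed a genome sequence and was not run. Fragment counts were not recovered from the values, so no counting intervals or detection limits are given. A gene listed at 0 can be a failed estimate, and zeros are described only as listed at 0.

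Identifiers were matched to symbols with a table of Ensembl identifiers, which named 45139 rows and left 934 without a symbol. Gene classes and coordinates came from NCBI RefSeq for GRCm38.p6, the same assembly as mm10, matched by symbol. RefSeq listed 20631 of the rows as protein coding. Mitochondrial genes were matched by name to RefSeq, and the strand of each mitochondrial gene was taken from textbook knowledge.

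A gene was called detected at 1 FPKM or more. There were 28 gene lists and 48 gene pairs, fixed before the data were examined. For each list the median FPKM of its members was set against the medians of 10000 random lists of the same size, drawn from all rows. Lists at or above the 97.5th percentile were called high and those at or below the 2.5th percentile low, as a description of this sample, since genes are not replicates. The percentile limits were set after the file was seen. For each pair the ratio of FPKM and the difference of log2(FPKM + 1) were computed. Pairs were counted as apart when they differed 2-fold on the log2(FPKM + 1) scale, a limit also set after the file was seen. This scale understates differences that involve low genes.

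The rule for the genes named in the text was fixed with the lists. It takes all members of both DNA methylation lists, the genes of the pairs, the 3 highest and 2 lowest members of every other list, and the 15 highest rows. The 15 highest nuclear protein-coding genes were added after the highest rows proved to be mitochondrial. Some genes that the rule takes are not reported here, while the counts and medians of the lists and pairs include all members. Alternatives for the floor, the pseudocount, the scaling, the summary of a list and the background of the random lists were computed.

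The list procedure was tested on simulated lists, with the 14510 detected genes as the background in place of all rows. Of 100 random lists of 15 detected genes 2 were called high or low. These lists came from their own background, so few calls were set in advance by the percentile limits. Of 20 lists drawn from genes at 4 or more times the median of detected genes 20 were called high. This check does not cover the calls made against all rows. Geometric means were taken on the log2(FPKM + 1) scale. The search for steps in low values took values within 0.01% of each other as equal, a limit set after the values were seen, and recovered the 3 simulated step sizes with an error of 0% on 975 genes. A simulated pooled library put 80 values at 2 times its smallest step and at most 2 at another step, on 1002 genes, and the simulated mean of 3 libraries put 15 and at most 42 there, on 975 genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.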

Results

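RNA-seq of the mPFC of untreated mice was examined as 1 expression value per gene, in FPKM, for 46073 genes. The series title gives the study's subject as methylated regions of this tissue, and the methylation data were not analysed here. Of these genes, 14510 (31.5%) were at 1 FPKM or more, 6721 were at 10 FPKM or more and 723 at 100 FPKM or more. Another 17126 genes (37.2%) were listed at 0. Among protein-coding genes 12081 of 20631 (58.6%) were detected, with a median of 9.86 FPKM among those detected, and 3224 were listed at 0. Long non-coding RNA genes were detected less widely, at 508 of 3189 (15.9%), and pseudogenes at 84 of 5599. There are no replicates in the table, so no value below has an error, and a ratio between genes compares 2 values from 1 table.

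The sequencing depth is unknown, so no counting interval is given. Where whole fragments are counted, a fragment is worth a fixed amount once FPKM is multiplied by the effective length, and the low values were examined for such steps. In 1547 genes of mostly single-exon classes (pseudogenes and olfactory, vomeronasal and taste receptors of 500 to 1500 bases), FPKM times the length less 204 bases took the same value in several genes. These repeated values were 3.19, 5.00 and 5.66 FPKM × bases, with 22, 13 and 8 genes within 0.01% of them. The larger steps were 1.57 and 1.78 times the first. At 2 times the first step there was 1 value within 0.01% and 9 within 0.4%, where the figure shows a broader peak. Most larger values lay at no sum of the steps.

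**Figure D1:**
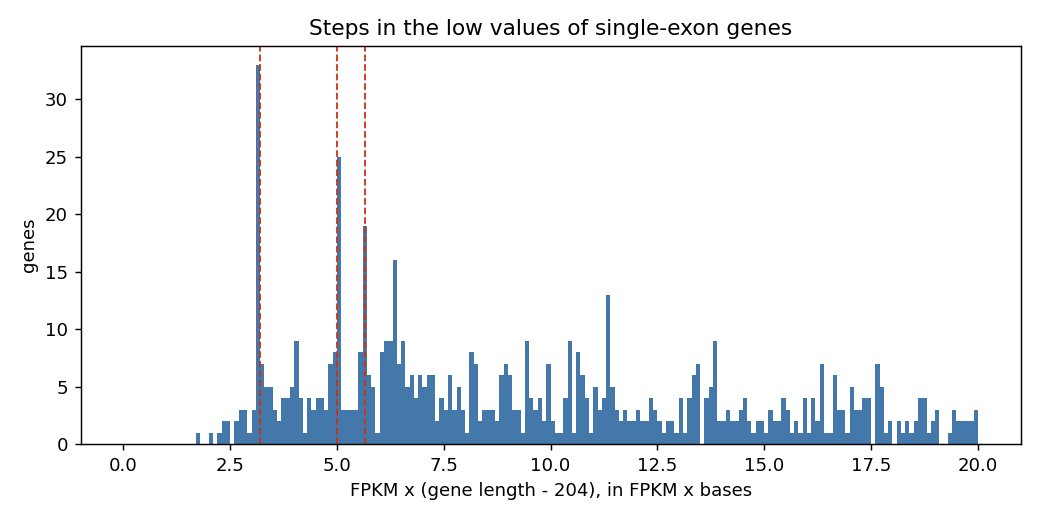
Histogram of FPKM times gene length less 204 bases (x axis, FPKM × bases, up to 20) against the number of genes (y axis) for single-exon gene classes. Dashed lines mark the 3 repeated values of 3.19, 5.00 and 5.66, with 22, 13 and 8 genes within 0.01% of them.

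The highest nuclear protein-coding genes included genes of synaptic release, calcium signalling, glycolysis, myelin and lipid transport. Snurf, which shares a bicistronic transcript with Snrpn, was listed highest at 2099.8 FPKM, and Snrpn itself at 341 FPKM. Reads of these overlapping genes cannot be divided with certainty. Fth1, the heavy subunit of the iron store ferritin, stood at 1379.5 FPKM and Snap25, a SNARE protein of synaptic vesicle release, at 1279 FPKM. The calmodulin genes Calm3 and Calm2, which encode the same protein, stood at 1259.8 and 1032 FPKM. Apoe, the main lipid carrier of the brain, was at 1123 FPKM. The glycolytic enzyme gene Aldoa was at 1065 FPKM, Gnas, the stimulatory G protein subunit, at 1061 FPKM and Rpl13a, a ribosomal protein, at 1057 FPKM. Ppia, Cst3, Uchl1, Cox7b, Mbp and Atp1b1 followed between 992 and 881 FPKM. Ppia, Rpl13a and the calmodulins have close paralogs or pseudogenes, so their values are uncertain.

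All 15 rows with the highest FPKM were mitochondrial, 14 of them tRNAs. The tRNA genes mt-Tc and mt-Te were listed at 62908 and 61119.9 FPKM, mt-Ty at 42475 and mt-Ta at 35047 FPKM, against 4266 FPKM for mt-Nd1, the highest mitochondrial mRNA. The other tRNAs of that group, from mt-Tn at 34630.4 FPKM through mt-Tl1, mt-Tp, mt-Tm, mt-Tq, mt-Tg, mt-Ts2, mt-Tw and mt-Ti to mt-Tr, reached down to 4373 FPKM. The 22 mitochondrial tRNAs are 59 to 75 bases long and held 48.0% of all summed FPKM. Of the 13 mitochondrial mRNAs, 8 were listed at 0: mt-Co1, mt-Co2, mt-Co3, mt-Atp6, mt-Atp8, mt-Nd4, mt-Nd4l and mt-Cytb. The tRNA mt-Ts1 was listed at 0 too, and mt-Nd3 stood at 18.5 FPKM. All 16 nuclear genes of the respiratory chain list were detected, with a median of 246 FPKM, from Uqcrb at 85.2 and Sdhb at 88.3 to Cox8a at 486, Cox4i1 at 668 and Atp5b at 870.3 FPKM.

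**Figure D2:**
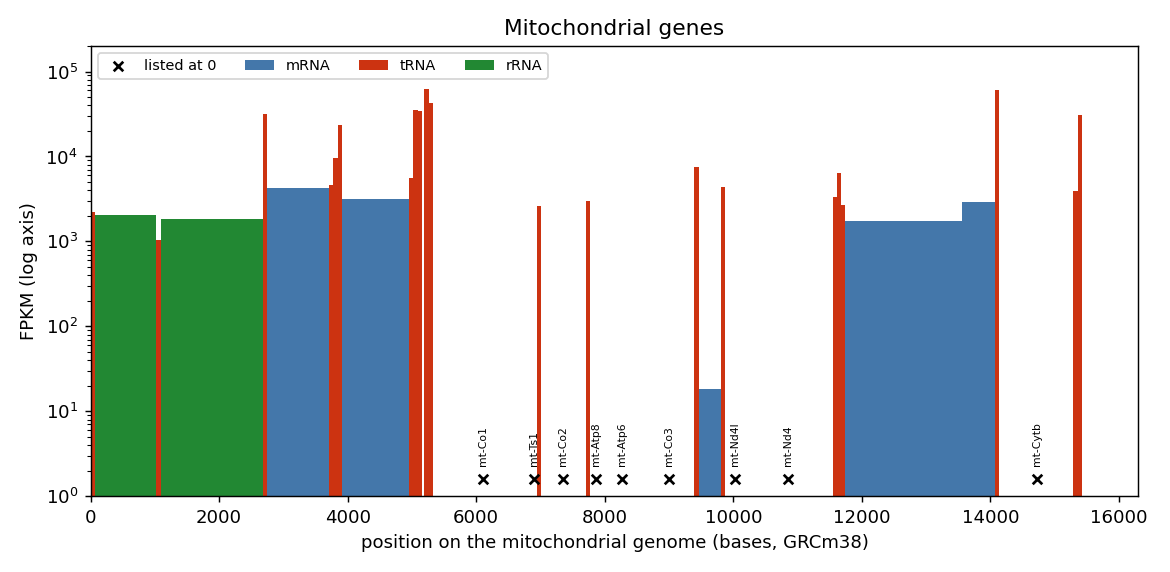
FPKM (y axis, log scale) of each mitochondrial gene drawn at its position (x axis, bases of the GRCm38 mitochondrial genome), with bars as wide as the gene and coloured by kind. Crosses mark the 9 genes listed at 0, and mt-Td and mt-Tk, between genes listed at 0, stand at 2589 and 3005 FPKM.

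Among DNA methyltransferase genes Dnmt1 and Dnmt3a were detected and Dnmt3b was not, and every Mbd and Zbtb gene of the list was detected. Dnmt1, the maintenance methyltransferase (chromosome 9, 20907206 to 20959888, GRCm38), was at 7.88 FPKM. Dnmt3a, a de novo methyltransferase (chromosome 12, 3801559 to 3914443), was at 6.60 FPKM, within 1.19-fold of Dnmt1. Dnmt3b, its paralog (chromosome 2, 153649411 to 153687730), was at 0.155 FPKM, so that Dnmt3a was 42.7-fold and Dnmt1 50.9-fold higher. Dnmt3l, the catalytically inactive cofactor, was at 0.461 FPKM. Uhrf1, which brings Dnmt1 to replicating DNA, was at 0.246 FPKM, and its paralog Uhrf2 was 64.7-fold higher at 15.9 FPKM. In the list, 13 of the 16 writers and readers were detected, with a median of 7.001 FPKM, and the genes under the floor were Dnmt3b, Dnmt3l and Uhrf1.

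Among the Mbd genes of the writers and readers list, Mbd3, a subunit of the NuRD complex, was highest at 60.6 FPKM (chromosome 10, 80392539 to 80399531). Mbd2 stood at 27.1 FPKM, 2.23-fold below Mbd3, and Mbd1 at 6.57 FPKM. Mbd5 was at 19.6, Mbd6 at 7.40 and Mbd4, a glycosylase, at 2.08 FPKM. Of the zinc finger readers, Zbtb4 was at 22.9, Zbtb38 at 6.52 and Zbtb33 at 4.75 FPKM.

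Of the oxidising enzymes that start demethylation, Tet2 (chromosome 3, 133463677 to 133545136) was at 3.94 FPKM and Tet3 (chromosome 6, 83362373 to 83457208) at 3.22 FPKM. Tet2 was 1.22-fold above Tet3. Tet1 (chromosome 10, 62804570 to 62887469) was at 0.931 FPKM, 4.23-fold below Tet2 and 3.46-fold below Tet3. The glycosylase Tdg, which removes oxidised cytosine, was at 8.99 FPKM, 3.00-fold above Smug1 at 2.99 FPKM, and Ung was at 0.831 FPKM. Gadd45g and Gadd45b, linked to repair-based demethylation, were at 8.30 and 5.57 FPKM and Gadd45a at 2.44 FPKM, 2.28-fold below Gadd45b. The cytidine deaminases were low: Apobec3 at 2.01, Apobec1 at 1.13 and Apobec2 at 0.193 FPKM. The repair endonuclease Apex1 was at 18.6 FPKM, and Idh2 and Idh1, which make the Tet cofactor 2-oxoglutarate, were at 26.2 and 13.8 FPKM. In all, 12 of 16 members of this list were detected, with a median of 3.11 FPKM.

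**Figure D3:**
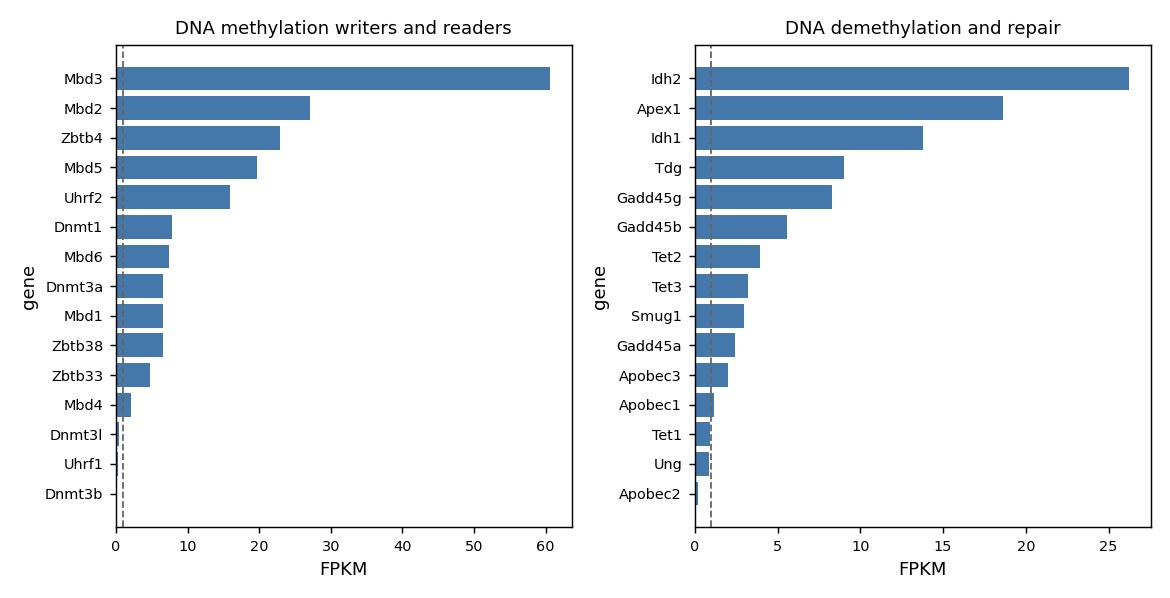
FPKM (x axis, linear) of the genes reported here (y axis) from the DNA methylation writers and readers (left) and of the DNA demethylation and repair list (right). Bars are single values with no replicates, the dashed line is the floor of 1 FPKM, and Dnmt3b (0.155), Apobec2 (0.193), Uhrf1 (0.246), Dnmt3l (0.461), Ung (0.831) and Tet1 (0.931) lie below it.

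Histone deacetylases and methyltransferases were detected in 19 of 20 cases, with a median of 7.53 FPKM. The class IV deacetylase Hdac11 was highest at 63.2 FPKM, followed by the histone H3 lysine methyltransferase Ehmt2 at 48.6 and Hdac5 at 41.1 FPKM. Ehmt2 was 5.98-fold above its partner Ehmt1, Hdac5 6.55-fold above Hdac4, and Hdac2 4.72-fold above Hdac1, while Hdac3 and Hdac2 were within 1.13-fold. Ezh1 was 9.70-fold above Ezh2, the Polycomb methyltransferase of dividing cells, which stood at 1.82 FPKM. The meiotic methyltransferase Prdm9 was lowest at 0.853 FPKM.

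Of the cell type lists, the pan-neuronal and excitatory neuron lists had the highest medians. The pan-neuronal list had a median of 139 FPKM over 12 of 12 detected members, from Nefh at 9.61 and Elavl4 at 30.6 to Syt1 at 303, Eno2 at 499 and Snap25 at 1279 FPKM. Snap25 was 228-fold above Snap23, its widely expressed paralog. The excitatory list had a median of 65.7 FPKM (10 of 10 detected), led by the calmodulin-binding protein gene Nrgn at 874, the kinase gene Camk2a at 701 and the vesicular glutamate transporter gene Slc17a7 at 353 FPKM. Emx1, at 7.08 FPKM, was its lowest member. Camk2a was 3.92-fold above Camk2b. Slc17a7 was 125-fold above Slc17a6, the transporter typical of subcortical neurons. The inhibitory list had a median of 21.4 FPKM (16 of 16 detected), 3.07-fold below the excitatory list. The neuropeptide genes Cck at 301 and Sst at 297 FPKM, with the membrane protein gene Lamp5 at 153 FPKM, led it, and Dlx5 at 1.44 and Adarb2 at 3.35 FPKM were lowest. Sst was 7.47-fold above Pvalb and 13.8-fold above Vip, and Gad1 was 5.98-fold above Gad2. These are ratios of RNA levels, not of cell numbers.

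The astrocyte and oligodendrocyte lists had medians above that of the inhibitory list, and the precursor and microglia lists had medians below it. Astrocyte markers had a median of 54.3 FPKM (12 of 12 detected), with the glycolytic Aldoc at 613, glutamine synthetase Glul at 606 and the glutamate transporter gene Slc1a2 at 184 FPKM, and with Sox9 at 4.66 and Aqp4 at 14.6 FPKM. Slc1a2 was 1.67-fold above Slc1a3, and Gfap 3.44-fold above Aldh1l1. Oligodendrocyte markers had a median of 36.6 FPKM (12 of 12 detected), with the myelin genes Mbp at 912 and Mobp at 204 FPKM among the highest, with Myrf at 8.11 and Ugt8a at 8.36 FPKM lowest. Mbp was 29.6-fold above Mog. Oligodendrocyte precursor markers had a median of 5.20 FPKM (8 of 8 detected), 7.03-fold lower, with Olig1 at 20.9, Sox10 at 10.1, Pdgfra at 6.31, Neu4 at 1.98 and Cspg4 at 1.66 FPKM. Microglia markers had a median of 17.4 FPKM (12 of 12 detected), from Tmem119 at 7.66 and Siglech at 9.22 at the low end to the complement genes C1qa at 39.0 and C1qb at 39.7 FPKM among the highest. Endothelial and mural markers had a median of 5.15 FPKM (14 of 14 detected), 27.0-fold below the pan-neuronal list, with Vtn at 27.8, Ly6c1 at 19.9, Rgs5 at 13.0, Kdr at 1.40 and Kcnj8 at 1.11 FPKM.

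**Figure D4:**
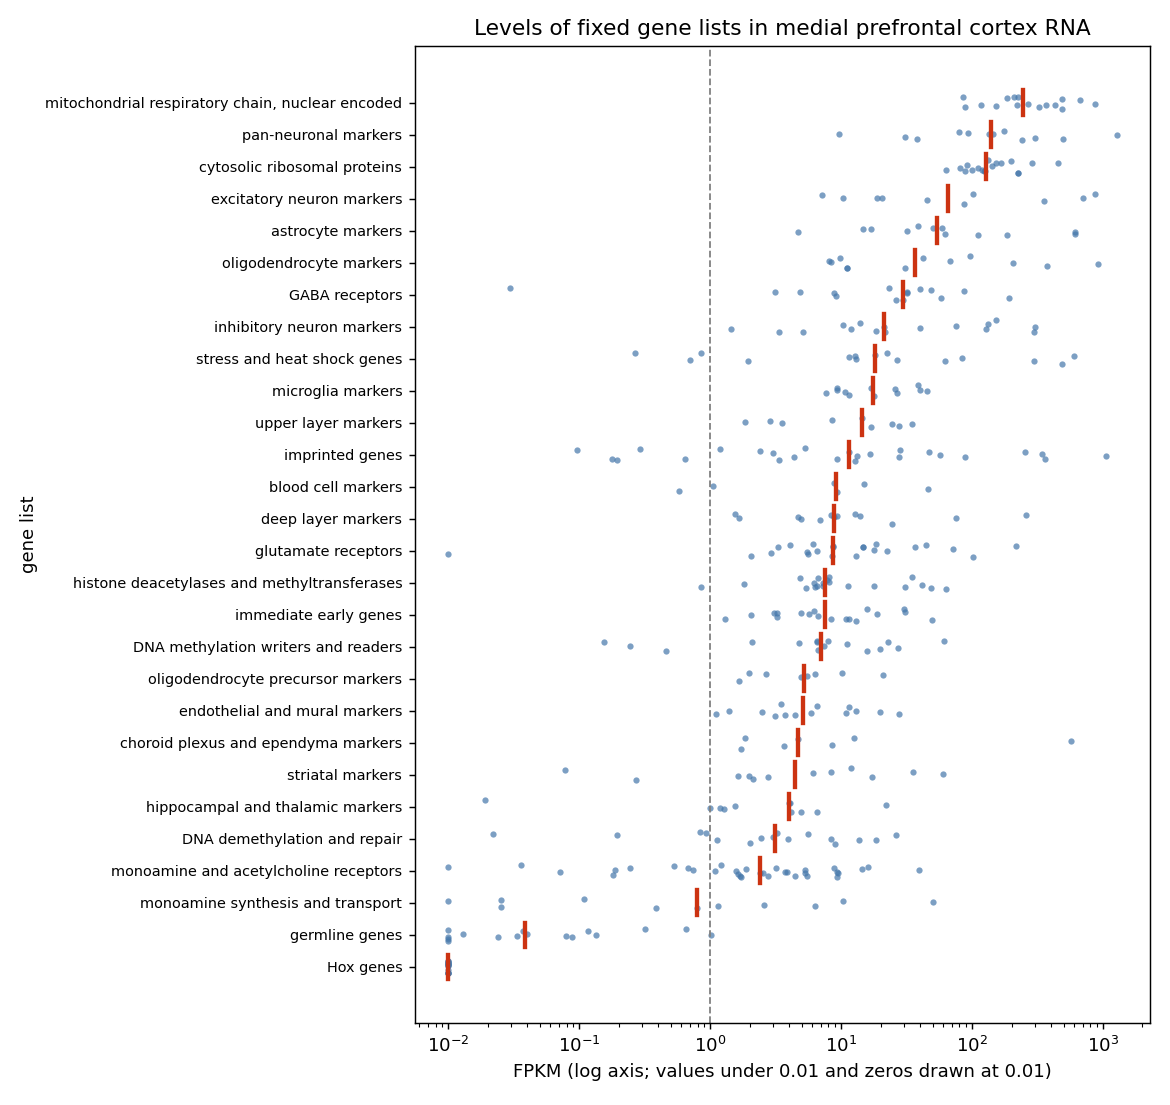
FPKM (x axis, log scale) of the members of each of the 28 gene lists (y axis), with 1 point per gene and the list median as a vertical red bar. The nuclear respiratory chain list (median 246 FPKM) and the pan-neuronal list (139 FPKM) are highest, and the medians of the monoamine synthesis, germline and Hox lists lie below the dashed floor of 1 FPKM.

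Markers of cortical layers were present for both upper and deep layers. The upper layer list had a median of 14.5 FPKM (9 of 9 detected), with Rasgrf2 at 35.0, Calb1 at 27.5 and Lhx2 at 24.5 FPKM highest and Rorb at 1.84 and Pou3f2 at 2.85 FPKM lowest. The deep layer list had a median of 8.76 FPKM (13 of 13 detected), with Pcp4 at 258, Crym at 75.8 and Rprm at 24.6 FPKM highest and Foxp2 at 1.54 and Ntsr1 at 1.66 FPKM lowest. The median of the upper list was 1.66 times that of the deep list. The geometric means had the opposite order, at 10.5 FPKM for the upper and 11.5 FPKM for the deep list. Which list is higher therefore depends on the summary used. Cux2, an upper layer transcription factor, was 1.31 times Fezf2, a deep layer one.

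Lists for other tissue that a dissection could hold had medians between 3.98 and 9.12 FPKM. Striatal markers had a median of 4.45 FPKM (10 of 12 detected), 14.8-fold below the excitatory list. Ppp1r1b at 59.6, Penk at 35.3 and Tac1 at 17.3 FPKM, which cortical neurons also express, were highest, and the striatal transcription factors Six3 and Isl1 were at 0.272 and 0.0772 FPKM. Hippocampal and thalamic markers had a median of 3.98 FPKM (9 of 11 detected), with Spink8 at 22.0, C1ql2 at 6.57 and Prkcd at 4.96 FPKM highest and Tcf7l2 at 0.990 and Gbx2 at 0.0192 FPKM lowest. Choroid plexus and ependyma markers had a median of 4.72 FPKM (7 of 7 detected) and a geometric mean of 9.62 FPKM. In that list Ttr, the thyroid hormone carrier, was at 566 FPKM, 45.2-fold above Folr1 at 12.5 FPKM, and Kcnj13 was at 8.57, Foxj1 at 1.84 and Ccdc153 at 1.72 FPKM. Blood cell markers had a median of 9.12 FPKM (5 of 6 detected), with the globin genes Hbb-bs at 46.4, Hba-a1 at 15.04 and Hbb-bt at 9.37 FPKM, Alas2 at 1.05 and the leukocyte gene Ptprc at 0.577 FPKM. The globin copies share sequence, so their split is uncertain.

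Of 23 glutamate receptor genes 22 were detected (median 8.63 FPKM), led by the obligatory NMDA receptor subunit Grin1 at 217 and the AMPA receptor subunits Gria2 at 101 and Gria1 at 71.3 FPKM. Gria2 was 1.42-fold above Gria1. Grin2b was 1.71-fold above Grin2a, and Grin1 was 14.7-fold above Grin2b. Grm6, a receptor of retinal bipolar cells, was lowest at 0.00253 FPKM, and Grin2d was at 2.05 FPKM. Of 15 GABA receptor genes 14 were detected (median 29.8 FPKM), led by Gabbr1 at 191 FPKM. Gabra6, a cerebellar subunit, was at 0.0293 FPKM and Gabrg3 at 3.15 FPKM. The neuronal chloride exporter gene Slc12a5 was 13.0-fold above the importer gene Slc12a2.

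Monoamine and acetylcholine receptors were lower, with a median of 2.39 FPKM and 24 of 33 detected. The muscarinic receptor genes Chrm1 at 39.4 and Chrm3 at 15.9 FPKM and the nicotinic subunit Chrnb2 at 14.4 FPKM were highest, and Adra2b at 0.0361 and Drd3 at 0.00255 FPKM lowest. The dopamine receptor genes Drd1, Drd5 and Drd2 differed by less than 2-fold. Drd1, at 2.77 FPKM, was 1.64-fold above Drd5 and 1.70-fold above Drd2. Htr2c, Htr2a and Htr1a were at 5.25, 4.44 and 3.86 FPKM, and Adra1a was 1.11 times Adra2a. Genes for monoamine synthesis and transport had a median of 0.800 FPKM and a geometric mean of 1.84 FPKM, with 5 of 11 detected. The degrading enzymes Maob at 10.4 and Maoa at 6.35 FPKM were among the highest, and the transporters Slc6a4 at 0.0253 and Slc6a2 at 0.00520 FPKM lowest. Maob was 1.64-fold above Maoa.

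Immediate early genes, which follow neuronal activity, were all above the floor (18 of 18, median 7.49 FPKM). Egr1 was at 49.6, Homer1 at 30.8 and Arc at 30.3 FPKM, and Fosb at 2.04 and Egr2 at 1.31 FPKM were lowest. Values are per gene, so isoforms of a gene such as Homer1 were not told apart. Egr1 was 4.56-fold and Arc 2.78-fold above Fos. Bdnf, a growth factor of this list, was 4.33-fold above Ntf3, and its receptor gene Ntrk2 was 3.65-fold above Ntrk3. The stress and heat shock list had a median of 18.2 FPKM (12 of 15 detected). The constitutive chaperones Hsp90ab1 at 596, Hspa8 at 484 and Hsp90aa1 at 299 FPKM led it, while the inducible Hspa1a was at 0.701 FPKM and Atf3 at 0.269 FPKM. Hspa1a has a near-identical copy, so its value is uncertain. The stress hormone receptor genes Nr3c1 and Nr3c2 were within 1.20-fold, and Crhr1 was 17.0-fold above Crhr2.

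Germline genes were nearly undetected, and imprinted genes ranged from 0.0966 to 1061 FPKM. Of 16 germline genes 1 passed the floor, Dazl, an RNA-binding protein of germ cells, at 1.02 FPKM (chromosome 17, 50279393 to 50293620). Ddx4 followed at 0.657 and Sycp3 at 0.316 FPKM, and Sycp1 and Dppa3 were listed at 0. No Hox gene passed the floor: 11 of 15 were listed at 0, Hoxa2 among them, and the highest, Hoxc8, Hoxa3 and Hoxb4, were at 0.00832, 0.00809 and 0.00614 FPKM. Of 25 imprinted genes 20 were detected, with a median of 11.5 FPKM. Gnas at 1061, the non-coding Rian at 358 and Snrpn at 341 FPKM were highest, and Kcnq1ot1 at 0.178 and H19 at 0.0966 FPKM lowest. Several imprinted loci hold overlapping or antisense transcripts, and the use of strand in counting is not stated, so Gnas, Rian, Kcnq1ot1 and Snrpn are uncertain. The ribosomal protein list, whose genes have many pseudogenes, had a median of 129 FPKM (18 of 18 detected), from Rpl5 at 63.7 and Rps6 at 80.9 to Rpl8 at 225, Rpl32 at 286 and Rplp1 at 454 FPKM.

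Against random lists drawn from all rows, whose median gene was at 0.0414 FPKM, 23 of the 28 lists had a high median and none a low one. The other five were oligodendrocyte precursor, choroid plexus and ependyma, monoamine synthesis, germline and Hox lists, at the 97.0th, 95.9th, 88.9th, 44.9th and 7.645th percentile. Of all rows 31.5% were detected, against 58.6% of protein-coding rows, so the background of all rows favours high calls for lists of protein-coding genes. Against protein-coding rows 11 lists were high and 2, the germline and Hox lists, were low. The striatal, hippocampal and thalamic, and blood cell lists, high against all rows, were then at the 68.9th, 64.5th and 83.55th percentile. Across the 48 fixed pairs, 31 differed at least 2-fold on the log2(FPKM + 1) scale, with the first gene higher in 29 and the second in 2, among them Sst over Pvalb. None of these differences could be set against the spread between animals.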

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

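The alternatives for protein-coding rows, for scaling without mitochondrial genes, for a protein-coding background, for ratios without a pseudocount, for a 4-fold limit and for the tolerance on low-value steps were chosen after seeing the data. The count of detected genes, 14510, was 20506 at a floor of 0.1 FPKM and 9571 at a floor of 5 FPKM. It was 12081 among protein-coding genes, 15138 after scaling to transcripts per fixed total (TPM) and 16893 when mitochondrial genes were left out of that scaling. Of the 48 pairs, 31 were 2-fold apart, 32 with a pseudocount of 0.1, of 0.01 or none, 25 among the 42 pairs with both genes at 1 FPKM or more, and 19 at a 4-fold limit. The number of lists that stood apart fell from 23, all high, to 13 with the background of genes at 1 FPKM or more (8 high and 5 low) and to 13 with protein-coding genes (11 high and 2 low). The detected background holds no gene under the floor, while the lists do, so it favours low calls. With it the call of the DNA demethylation and repair list reversed, from the 98.7th to the 0.42nd percentile. That of the monoamine and acetylcholine receptor list reversed too, from the 99.8th to the 0th percentile. Against protein-coding genes these lists were at the 56.87th and 46.855th percentile, neither high nor low. With a geometric mean in place of the median, 24 of 28 lists were within 1.5 times. The germline list crossed the median of all rows, from 0.0385 to 0.136 FPKM. Its highest members, Dazl at 1.02, Ddx4 at 0.657 and Sycp3 at 0.316 FPKM, raise a mean on the log2(FPKM + 1) scale. How high they lie leaves the median unchanged. The choroid plexus list went from 4.72 to 9.62 FPKM, the monoamine synthesis list from 0.800 to 1.84 FPKM, across the floor, and the Hox list from 0 to 0.00176 FPKM. The share of larger values at sums of the low-value steps went from 3.92% to 18.2% at a tolerance of 0.4%. Leaving out libraries, limma without moderation, a floor on the mean over libraries, the spread and shift between libraries and the promoter classes were not run, since the table holds 1 value per gene and no genome sequence was used here. No paired analysis was possible because the table holds 1 value per gene. No limit set by depth was computed, as fragments are not given. The lowest values may rest on few fragments, so their order is uncertain.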

Other observations

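The tests in this part were chosen after the results were seen, except the second choroid plexus list, whose genes and prediction were written before their values were looked at.

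A second list of 12 genes typical of choroid plexus, the epithelium that makes cerebrospinal fluid, was present at low level in the tissue. Of these, 11 were at 1 FPKM or more, with a median of 2.05 FPKM, against 1 of 12 genes typical of liver, kidney, muscle, gut, lung, skin and pancreas, with a median of 0.0753 FPKM. Slc13a4 was at 3.797, Calml4 at 2.75, Sostdc1 at 2.69, Kcne2 at 2.45, Otx2 at 1.82 and Cldn2 at 1.68 FPKM. Enpp2 was at 148 FPKM, but oligodendrocytes express it too. Steap1, at 0.995 FPKM, was the one member under the floor.

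Ttr, at 566 FPKM, was far above the other choroid plexus markers. A candidate source is RNA from choroid plexus carried over in the dissection, and 11 of 12 genes of the second list at the floor is what that source predicts. The count does not single out this source. Of all protein-coding genes 58.6% were at 1 FPKM or more, and their median of 2.58 FPKM was above the 2.05 FPKM of the second list. Striatal markers reached the floor in 10 of 12 cases and hippocampal and thalamic markers in 9 of 11. Expression of these genes by other cells of the tissue was not tested and stays open, as does a biological explanation, for which the design gives no group. With 1 value per gene, it cannot be seen whether Ttr came from 1 animal.

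Mitochondrial mRNAs were listed at 0 in 8 cases, with mt-Ts1. Fragments shared between overlapping genes are argued against as the whole cause. The mRNAs mt-Nd1, mt-Nd2, mt-Nd5 and mt-Nd6 also overlap a neighbour, yet these 4 were above 100 FPKM, while mt-Co2 and mt-Cytb overlap none and were at 0. Absence of these transcripts stays open. The tRNAs mt-Td and mt-Tk, between genes listed at 0, were at 2589 FPKM or more, but they are separate RNAs and do not measure the mRNAs beside them. A failed estimate at loci with very many fragments may be the reason. It predicts zeros among other abundant genes, and 0 of the 34 members of the nuclear respiratory chain and ribosomal protein lists were at 0. It stays open too, because a limit that only mitochondrial loci passed would leave those genes untouched, and no status of the estimate was used here.

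The mitochondrial tRNAs took 48.0% of summed FPKM, and length correction is a candidate explanation. For their level, the values alone cannot tell it apart from a true abundance. The longest tRNA has 75 bases and the shortest other mitochondrial gene 204, so length and kind of gene go together. Whether the library preparation retains RNAs as short as these was not examined. For the differences between tRNAs, length alone is argued against. At each of the 4 lengths shared by 3 or more tRNAs, the highest was at least 3.36-fold above the lowest, and 58.3-fold at 69 bases. Scaling to TPM without mitochondrial genes gave 16893 detected genes, against 15138 with them.

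The 7 light-strand tRNAs with a value had a median of 35047 FPKM (9516 to 62908), and the 14 heavy-strand tRNAs a median of 4129 FPKM (1049 to 31564). The light-strand mt-Ts1 was listed at 0 and is in neither median. Strand here is that of the gene. The use of strand in counting is not stated, so these medians do not show which strand the fragments came from. The strand was looked at after the highest values were seen, and mt-Ta, mt-Tn, mt-Tc and mt-Ty are neighbours, so the difference was not tested.

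The repeated low values may show that each deposited value is a mean over 3 libraries. Of 434 larger values in the single-exon classes, 3.92% lay within 0.01% of a sum of 2 or 3 of the steps, against a 95th percentile of 0.691% for 1000 random triples of steps. With both end steps kept and the middle one drawn at random, the 95th percentile was 1.61%. A first tolerance of 0.4% mixed repeated with scattered values, and gave 18.2% against 95th percentiles of 14.0% and 16.1%. The comparison with random steps was tried in 3 forms, and a simulated pooled library passed it too, so it does not by itself tell 3 libraries from 1. A mean over 3 libraries also needs values at 2 times the smallest step. There was 1, while a simulated mean of 3 libraries put 15 there. The step sizes and gene levels of that simulation were assumed and not fitted to these data, so 15 is not an expected count here. Away from the steps, at most 2 genes shared a value between 1 and 2 times the smallest step. At the tolerance of 0.4% there were 9 values at 2 times the smallest step, and their spread was not explained. Most larger values lay at no sum, and the reason was not tested, so the mean over 3 libraries stays open. A single pooled library counted in whole fragments is argued against, since it gives only multiples of its smallest step, and 13 and 8 genes shared values at 1.57 and 1.78 times that step, against at most 2 genes at any other value between 1 and 2 times that step. This comparison replaced 2 earlier ones, the ratio of the steps and the count at 2 times the smallest step, which could not decide. The steps were noticed by eye before they were tested.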
